A study of Arabidopsis thaliana with 27 samples.

How the data were processed

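Total RNA of a habituated suspension culture of Arabidopsis thaliana (Col-0) was extracted with Trizol, converted to biotinylated cRNA and read on single-colour Affymetrix arrays, per the labels' protocols. The 27 arrays cover 9 times, every 12 h from 0 h to 96 h, in 3 time-courses lettered A, B and C, and each array was assigned to its time and letter from its title. The series' design text calls the time-courses independent and compares each time with 0 h.

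The deposited values are the authors' log2 values after RMA, a method that corrects background, normalizes between arrays and summarises the probes of a probe set, per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. The base of the logarithm is not stated either and was taken as 2 from the range of the values, and fold changes rest on that choice. In every array 272 to 978 values were exactly 0, the lowest value of the table, so that low signals stop at a floor and changes that start or end there are understated. How the floor arose is not recorded. Array medians lay between 0.86 and 1.00, the highest value was 12.3, and correlations between arrays of the same time were 0.936 or more. For arrays, the number of arrays limits the precision.

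Of 22810 probe sets, 64 control probe sets and 3 with an empty value were left out, and 22743 were tested. The platform annotation at hand lists 14016 probe sets, 13513 with 1 gene and 503 with several. Of the tested probe sets, 8729 are not listed and are unnamed here, which does not mean that they lack a gene. Of the probe sets with 1 gene, 13436 were matched to a reference gene table of assembly TAIR10.1, which served for gene names alone. The values name no genome build, so that no coordinates are given. For each of 13354 genes the probe set with the highest mean over all arrays stood for the gene.

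A linear model with 1 mean per time was fitted to all 27 arrays with limma (lmFit, contrasts and eBayes with defaults), so that all times share 1 estimate of the spread. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 in a comparison are called changed. The comparisons were each later time with 0 h, 72 h with 48 h, 96 h with 72 h, and a moderated F test over all times. These p-values rest on the spread of arrays around their time means, pooled over all times and with arrays taken as independent. Arrays that share a letter were correlated, as given below, and the spread at the times compared can differ from the pooled one. Values after ± are standard errors of log2 differences from that fit unless SD is written. All 170 called values of named genes in the 5 comparisons to which the rule for names applies had the same direction in 3 of 3 time-courses. For the genes that rose or fell most the rule itself required this. Gene lists were tested with camera from limma, with a preset correlation between genes of 0.01, adjusted over lists and comparisons, and again with the correlation estimated from the data. For 60 h against 48 h, and for tests without the 96 h array of time-course A, adjustment was over the lists of that comparison alone. Adjusted p of those tests are therefore not on the same footing as the others. For lists fixed in advance, members were also counted after adjustment over the list alone.

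The tests, comparisons, 20 gene lists, rule for names and most alternatives were fixed before the data were examined. The rule names, at 12 h, 48 h and 96 h against 0 h, 72 h against 48 h and 96 h against 72 h, the 5 genes that rose most and the 5 that fell most among called genes with the same sign in all 3 time-courses. It also names the 4 members of each list with the largest absolute change, and 30 genes of xylem formation, division and hormone response in every case. At the other times the genes shown are taken from those this rule names in some comparison or names when applied there. Because the annotation covers part of the array, 52 of the 308 genes on these lists had a probe set of their own and 3 shared one. Of the genes to be named in every case 2 were measured, GH3.3 and ARR15, and no xylem transcription factor, laccase or brassinosteroid gene of the lists was. Of the 20 lists 10 had at least 3 measured members. A further 21 lists were written from gene names and general knowledge after the coverage of the annotation was seen and before any value of a gene was. For the lists of xylem and cell death genes it is not known whether published data on these cultures entered what was remembered.

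The letters pair the samples because the design text ties each letter to 1 time-course. Deviations from the time means had a median correlation of 0.246 over the 108 pairs of arrays that share a letter (from -0.06 to 0.724) and of -0.125 over the 216 pairs that share neither letter nor time. A fit with the letter as a block was run beside the fit without it. Other alternatives fixed in advance were centring arrays on their median, quantile normalization, leaving out dim probe sets (highest time mean below the 30th percentile), a 2-fold minimum, an adjusted p under 0.01, eBayes with trend and robust options, array weights, a fit to the 6 arrays compared, leaving out each array in turn, and for lists fry and the mean of a gene's probe sets. Alternatives chosen after seeing the data were the 3′ minus 5′ difference of the GAPDH control as a covariate, without and with the block, leaving out time-course B, leaving out the 5 arrays with a difference above 2.5, the genes and lists found without the 96 h array of time-course A, the mean squared differences from 0 h without that array or without each time-course, the comparison of 60 h with 48 h, and the overlaps and phosphate starvation genes with each array left out.

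The scripts were tested on simulated data for a comparison of 12 h with 0 h over 22743 probe sets, with the spread pooled over all times. There, 24 of 70 probe sets changed 2-fold, 63 of 70 changed 4-fold and 69 of 70 changed 8-fold were recovered, with 11 false calls. The F test recovered 14, 58 and 67 of them with 3 false calls. Recovery was counted by fold change alone. These figures do not cover dim probe sets or arrays correlated within a time-course. The list test camera called a list whose members had been moved and did not call a list left unmoved. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.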

Results

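Gene expression was measured while suspension-cultured cells of Arabidopsis thaliana (ecotype Col-0) formed tracheary elements, the dead, thick-walled cells that conduct water in xylem. Cells 7 days old were moved into fresh medium that held an auxin (NAA), a cytokinin (BAP) and a brassinosteroid (epibrassinolide). Total RNA was collected at 9 times, every 12 h from 0 h to 96 h, in 3 independent time-courses called A, B and C. Each of the 27 samples was read on its own single-colour array, so that every time had n = 3. The labels describe dividing cells at 0 h, an end of division and a start of expansion at 12 h, cells not yet depositing secondary wall at 48 h, deposition from 60 h, and completed walls with preparation for cell death at 96 h. Cultures moved to fresh medium without hormones were not analysed here, so each comparison with 0 h covers the medium and the hormones together. The log2 signals ran from 0 to 12.3, the array medians lay between 0.86 and 1.00, and the number of arrays limits the precision. The difference between the 3′ and 5′ probe sets of the GAPDH control, which grows when the 5′ part of transcripts is lost, was 2.99 to 4.38 log2 units on 5 arrays, all of time-course B (0 h, 60 h, 72 h, 84 h and 96 h), and 0.35 to 1.89 on the other 22. A second GAPDH pair, an actin pair and a ubiquitin pair of control probe sets also placed all 5 arrays above the other 22 (0.95 to 1.46 against -0.32 to 0.62, 3.88 to 5.03 against 1.74 to 3.02, and 1.95 to 2.14 against 1.01 to 1.64). Another actin pair placed 4 of the 5 above them (5.57 to 6.69 against 4.74 to 5.90) and was high on all 27 arrays.

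**Figure D1:**
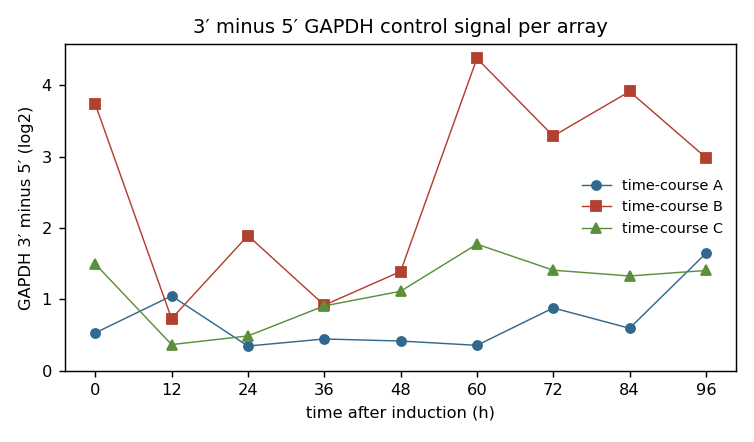
The 3′ minus 5′ log2 signal of the GAPDH control (vertical axis) is plotted against hours after induction for each array of time-courses A (circles), B (squares) and C (triangles). The 5 arrays of time-course B between 2.99 and 4.38 lie above the other 22.

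The comparison of 12 h with 0 h asked how the dividing cells responded soon after the transfer. GSTU22 and GSTU25, tau-class glutathione transferases, rose from near the floor by 8.33 ± 0.33 and 7.14 ± 1.00 log2 units (SE, n = 3). The dehydrin LTI30 rose by 6.94 ± 0.38, the OCT family transporter OCT5 by 6.77 ± 0.26 and AT3G26470 by 7.46 ± 0.21. GH3.3, which encodes an auxin-induced enzyme that conjugates auxin to amino acids, rose by 6.14 ± 0.22, and ARR15, a cytokinin-induced response regulator, by 2.21 ± 0.24. The largest falls among named genes were those of AT5G20790 (-7.74 ± 0.53), OCT1 (-6.40 ± 0.94), AT5G17340 (-6.32 ± 0.77), AT3G03150 (-5.61 ± 0.68) and AT4G39320 (-5.03 ± 0.78). Each of these 12 genes moved the same way in all 3 time-courses, with adjusted p of 6.77e-05 or less. The rule for names required that agreement of the 5 that rose most and the 5 that fell most, so for them it is no separate evidence. Of 22743 probe sets, 3900 changed, 1929 up and 1971 down (1947 and 1852 with arrays centred on their median).

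Genes of cell division fell at 12 h. The Aurora kinases AUR1 and AUR2, which act in mitosis, fell by 3.35 and 2.87 log2 units (SE 0.30 and 0.31), which made 2 of the 3 measured genes of mitosis and cytokinesis (3 when adjusted over the list alone; camera adjusted p = 2.93e-04). Of 28 chromosome replication and segregation genes 10 fell and 0 rose, among them 3xHMG-box2 (-4.18 ± 0.55) and UBC20 (-2.52 ± 0.36), with camera adjusted p = 2.87e-07. MCM7, the sole measured gene of the DNA replication list and part of the replicative helicase, fell by 1.13 (SE 0.20). Of 28 tubulin and cortical microtubule genes 12 fell and 0 rose, led by TUB5 (-3.73 ± 0.42), with TUB6 at -1.57 ± 0.29 (camera adjusted p = 1.26e-05). These 3 list calls held, at adjusted p = 0.031, 0.0465 and 0.00755 with an estimated correlation. The tubulin list fixed before the data had 3 of 7 members down (5 when adjusted over the list alone), with camera adjusted p = 0.00264 and adjusted p = 0.346 with an estimated correlation.

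Of 15 GH9 cellulases 5 fell and 0 rose at 12 h, among them GH9B8 (-4.13 ± 0.60) and GH9C2 (-3.16 ± 0.37), with camera adjusted p = 0.0015 and adjusted p = 0.0621 with an estimated correlation. Of 28 expansins and xyloglucan endotransglucosylases 8 fell and 1 rose, with XTH19 at -4.16 ± 0.65 and XTH16 at -3.90 ± 0.21 (camera adjusted p = 0.0073; adjusted p = 0.291 with an estimated correlation). The TBL wall acetyltransferase family had 2 of 22 members down, TBL39 (-2.95 ± 0.38) and TBL36 (-2.93 ± 0.33), and the list did not pass (camera adjusted p = 0.267). COB, which directs cellulose deposition and was the sole measured gene of primary wall cellulose synthesis, fell by 1.76 (SE 0.29). IRX15-L, which acts in xylan synthesis, fell by 3.31 (SE 0.33), the sole call among 3 secondary wall polysaccharide genes (1 when adjusted over the list alone; camera adjusted p = 0.16). Of 29 serine carboxypeptidase-like genes 9 fell and 0 rose, with SCPL34 at -3.71 ± 0.44 (camera adjusted p = 9.06e-04; adjusted p = 0.00898 with an estimated correlation).

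Of 47 UDP-glycosyltransferases 11 rose and 4 fell at 12 h, among them UGT87A2 (4.38 ± 0.29) and UGT73B5 (4.14 ± 0.15), with camera adjusted p = 0.00155 and adjusted p = 0.186 with an estimated correlation. Of 14 glutathione transferases 3 rose and 1 fell (camera adjusted p = 0.0655). Of 9 dehydration and cold proteins 3 rose, with LEA4-5 at 3.89 ± 0.49 (camera adjusted p = 0.0017; adjusted p = 0.0987 with an estimated correlation). Of 21 folding and heat chaperone genes 7 rose, among them HSA32 (2.11 ± 0.49) and the heat shock gene HSP22 (3.16 ± 0.73), and CRT1b fell by 2.15 (SE 0.25), with camera adjusted p = 0.103 for the list. In time-course A both heat genes stood near their 0 h level at 12 h (HSP22 at 1.00 against 0.88 and HSA32 at 3.02 against 2.98), while HSP22 reached 5.58 in B and 5.11 in C and HSA32 5.43 and 5.28. Of the 7 measured auxin response genes 2 rose, GH3.3 and IAA30 (2.41 ± 0.67), or 4 when adjusted over the list alone (camera adjusted p = 0.0116; adjusted p = 0.0447 with an estimated correlation). HCT, an enzyme of monolignol synthesis and the sole measured gene of that list, rose by 1.56 ± 0.41. The autophagy genes ATG8B and ATG8D both rose by 1.67 (SE 0.23 and 0.25), ATG8F fell (adjusted p = 6.04e-04 by limma, SE 0.29), and the list of 10 autophagy genes did not pass (camera adjusted p = 0.461). The limma call of IAA30 was lost without the 12 h array of time-course A (adjusted p = 0.101), and that of HCT without any of 3 arrays, with adjusted p up to 0.0777 without the 0 h array of time-course B. The mean 3′ minus 5′ GAPDH difference was 1.92 at 0 h and 0.72 at 12 h, and a fit to these 6 arrays alone called 2243 probe sets.

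**Figure D2:**
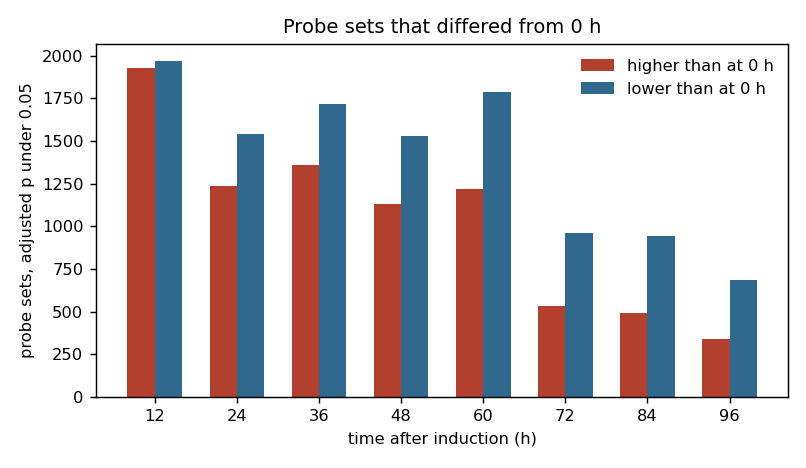
Numbers of probe sets with adjusted p under 0.05 that were higher (red bars) or lower (blue bars) than at 0 h are plotted against hours after induction. The 12 h bars stand at 1929 and 1971, and the 96 h bars at 340 and 685.

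At 24 h and 36 h the sets of genes away from their 0 h level had shifted. GSTU22 was back at 0.59 ± 0.22 log2 units at 24 h (SD, n = 3), against 8.82 ± 0.90 at 12 h and 0.50 ± 0.09 at 0 h, and LTI30 at 2.18 ± 0.67 against 8.03 ± 0.62 at 12 h. GH3.1, another auxin-induced GH3 enzyme gene, had risen by 4.43 ± 0.42 (SE) at 24 h, the MADS-box gene AGL28 by 4.43 ± 0.36 and the peroxidase gene AT2G34060 by 4.34 ± 0.61. EXPA8, an expansin, rose by 2.63 ± 0.27, and 2 of the 4 measured wall loosening genes rose (2 when adjusted over the list alone), with camera adjusted p = 0.02 and adjusted p = 0.0724 with an estimated correlation. EXPA9 and EXPA15 lay near the floor on every array (at most 0.89 and 1.25). There EXPA15 rose from 0.46, 0.83 and 0.69 at 0 h to 1.09, 1.25 and 0.98 at 24 h in A, B and C. EXPA4, the other member, was lower in C (10.08 at 0 h and 9.87 at 24 h), so the list result rests largely on EXPA8. AUR1 was still lower than at 0 h at 24 h (-1.24 ± 0.30), and at 36 h AUR1 and AUR2 no longer differed from 0 h (adjusted p = 0.759 and 0.698 by limma). Of 10 autophagy genes 3 fell at 24 h, with ATG8F at -3.91 ± 0.29 (camera adjusted p = 8.71e-05; adjusted p = 0.125 with an estimated correlation). Of 4 vacuolar processing enzymes, proteases of the vacuole, 2 fell, with BETA-VPE at -1.99 ± 0.37 (camera adjusted p = 0.0137; adjusted p = 0.06 with an estimated correlation). The auxin response list had 4 of 7 genes up at 24 h and at 36 h (4 when adjusted over the list alone at both), with adjusted p = 0.00939 and 0.0209 with an estimated correlation. In all, 2776 probe sets differed from 0 h at 24 h (1237 up, 1539 down) and 3075 at 36 h (1358 up, 1717 down). The balance of up and down at 36 h turned with scaling, to 1644 up and 1481 down with arrays centred on their median and 1553 up and 1517 down after quantile normalization. Without the 9 arrays of time-course B, a setting chosen after seeing the data, these counts were 1753 and 1560.

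**Figure D3:**
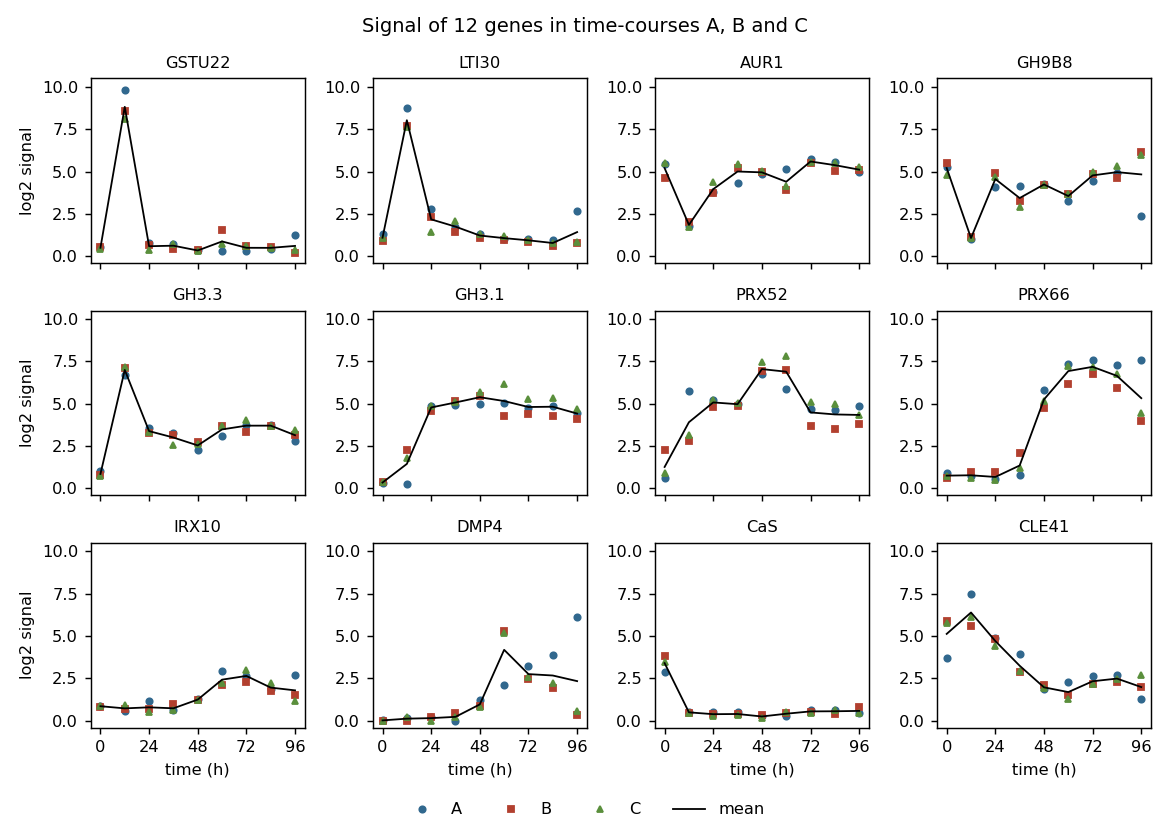
The log2 signal of 12 named genes (vertical axis) is plotted against hours after induction, with circles, squares and triangles for time-courses A, B and C and a line for the mean. GSTU22 stands at 8.82 at 12 h and 0.59 at 24 h, and DMP4 at 96 h separates the array of time-course A from the others.

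At 48 h, the last time that the labels place before secondary wall deposition, the peroxidase genes PRX52 and PRX66, both tied to lignification, had risen by 5.78 ± 0.63 and 4.50 ± 0.61 log2 units (SE, n = 3), and AT2G04850 by 6.59 ± 0.49. AT3G27200 rose by 5.69 ± 0.74, the subtilase gene SBTI1.1 by 5.27 ± 0.33, AT5G38610 by 5.24 ± 0.64 and GH3.1 by 5.04 ± 0.42. EXPA8 rose by 2.85 ± 0.27. The peroxidase gene PRXR1 fell by 5.85 (SE 0.41), and OCT1 (-6.81 ± 0.94), AT3G03150 (-6.16 ± 0.68), AT5G52390 (-5.06 ± 0.99) and AT5G13140 (-4.94 ± 0.44) also fell. CLE41, a peptide gene of the phloem side that holds vascular stem cells undifferentiated, fell by 3.16 (SE 0.50).

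The list of laccases and peroxidases had 5 measured members, all peroxidases. Of these 2 rose at 48 h (2 when adjusted over the list alone), with camera adjusted p = 0.00972 and adjusted p = 0.116 with an estimated correlation. The other members, PRX17, PRX71 and PRX72, stood at 0.60, 0.37 and 0.73 log2 units at 48 h, near the floor. The auxin response list had 3 of 7 up (4 when adjusted over the list alone; camera adjusted p = 6.18e-04; adjusted p = 0.00939 with an estimated correlation), with IAA29 at 2.04 ± 0.47. GH3.3 and ARR15 were 1.68 ± 0.22 and 0.90 ± 0.24 above 0 h, and the ARR15 call was lost without the 48 h array of time-course A (adjusted p = 0.109). Of 19 xylem co-expressed genes 3 rose and 1 fell, with AT1G79620 up by 3.72 ± 0.62 (camera adjusted p = 0.0073; adjusted p = 0.547 with an estimated correlation). The 3 secondary wall polysaccharide genes had a median of 0.39, a mean of -0.02 and a test direction of down, with camera adjusted p = 0.904, and IRX15-L stayed 1.70 log2 units below 0 h (-1.70 ± 0.33). Of 23 nuclear photosynthesis genes 9 fell, with CaS at -3.15 ± 0.16 and PSBY at -2.30 ± 0.29 (camera adjusted p = 1.78e-09; adjusted p = 0.0103 with an estimated correlation). ATG8F (-2.82 ± 0.29) and BETA-VPE (-2.37 ± 0.37) remained below 0 h. In all, 2660 probe sets changed (1133 up, 1527 down; 1320 up and 1285 down with arrays centred on their median), and 4032 with array weights. The mean 3′ minus 5′ GAPDH difference was 0.97 at 48 h, and without time-course B, chosen after seeing the data, 1388 probe sets changed.

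The labels place wall deposition from 60 h to 84 h. Between 48 h and 60 h, a comparison chosen after seeing the data, limma called 3 probe sets (2 up and 1 down, AT5G11420 and 2 unnamed here), with 2495 at an unadjusted p under 0.05. The count was 420 without the 60 h array of time-course A, 2 and 1 without those of B and C, and 0 without any of the 48 h arrays. In that comparison the xylem co-expressed, secondary wall polysaccharide and cell death lists had 0 of 19, 0 of 3 and 0 of 4 called, with camera adjusted p = 3.13e-08, 8.36e-04 and 0.00543 and adjusted p = 0.24, 0.24 and 0.443 with an estimated correlation. Against 0 h, at 60 h PRX66 had risen by 6.18 ± 0.61 log2 units (SE, n = 3) and PRX72 had risen as well (adjusted p = 1.38e-04 by limma, SE 0.33). IRX15 and IRX10, which act in xylan synthesis, rose by 2.65 ± 0.45 and 1.57 ± 0.29. DMP4, a membrane protein gene linked to senescence and cell death, rose by 4.17 ± 1.00, the aspartic protease gene PASPA3 by 1.89 ± 0.51, and EXI1 was called up near the floor (0.66 at 60 h). BETA-VPE was lower (-3.27 ± 0.37) while ALPHA-VPE rose by 1.83 ± 0.30. Of 19 xylem co-expressed genes, a list for which earlier use of these cultures cannot be ruled out, 13 rose at 60 h, 11 at 72 h and 7 at 84 h, among them AT1G79620 (5.13 ± 0.62 at 60 h) and AT3G52900 (4.49 ± 0.72 at 60 h). The camera adjusted p were 3.55e-08, 2.48e-10 and 7.19e-07, and all these list calls were lost, with adjusted p = 0.108, 0.06 and 0.155 with an estimated correlation.

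Of the 3 measured secondary wall polysaccharide genes 2 rose at 60 h, 72 h and 84 h (2 at each, with 1 down at 60 h, when adjusted over the list alone), and the list passed at 72 h alone among these times, with camera adjusted p = 0.0142 and adjusted p = 0.226 with an estimated correlation. IRX15-L, its other member, stood at -0.70 ± 0.33 against 0 h at 60 h without passing (adjusted p = 0.186 by limma). Of the 4 cell death genes 3 rose at 60 h (3 when adjusted over the list alone), with camera adjusted p = 0.0148 and adjusted p = 0.28 with an estimated correlation. At 72 h PASPA3 alone of them was called, with 1.90 ± 0.51 (2 when adjusted over the list alone), and DMP4 stood 2.73 ± 1.00 above 0 h without passing (adjusted p = 0.128 by limma), while the list had camera adjusted p = 0.0305 and adjusted p = 0.347 with an estimated correlation. At 84 h limma called 0 of the 4 (2 when adjusted over the list alone; camera adjusted p = 0.0667). Of the 5 peroxidases measured on the list of laccases and peroxidases 3 rose at 60 h (3 when adjusted over the list alone; camera adjusted p = 9.32e-04; adjusted p = 0.0448 with an estimated correlation). The auxin response list had 3 of 7 up at 60 h, 72 h and 84 h, GH3.1, GH3.3 and IAA29 at each (4, 4 and 3 when adjusted over the list alone), with adjusted p = 0.00603, 0.00103 and 0.00103 with an estimated correlation. In all, 3008, 1494 and 1434 probe sets differed from 0 h at 60 h, 72 h and 84 h. The mean 3′ minus 5′ GAPDH differences were 2.17, 1.86 and 1.95, and the 72 h and 84 h counts were 2266 and 2210 with that difference as a covariate, chosen after seeing the data. Without the 0 h array of time-course C the 72 h count was 993, and without the 84 h array of time-course A or C the 84 h count was 953 or 945.

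At 96 h the peroxidase genes PRX66 and PRX52 were still 4.58 ± 0.61 and 3.07 ± 0.63 log2 units above 0 h (SE, n = 3). AT3G27200 (4.25 ± 0.74), AT2G04850 (4.24 ± 0.49), AT5G38610 (4.02 ± 0.64) and GH3.1 (4.07 ± 0.42) were also up, and GH3.3 was up by 2.29 ± 0.22. GH9B13, a GH9 cellulase gene, rose by 2.34 ± 0.50. PRXR1 (-5.64 ± 0.41), AT5G13140 (-4.77 ± 0.44), AT2G43530 (-4.26 ± 0.70), the peroxidase gene AT3G21770 (-3.85 ± 0.39) and AT3G49220 (-3.79 ± 0.44) were lower, as was CLE41 (-3.14 ± 0.50). For PRX66, AT3G27200 and AT5G38610 the 96 h arrays lay far apart, with SD of 1.96, 2.73 and 2.37.

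Of the lists, auxin response had 3 of 7 genes up at 96 h (4 when adjusted over the list alone; camera adjusted p = 2.14e-06; adjusted p = 0.00103 with an estimated correlation). Of 19 xylem co-expressed genes 2 were up (camera adjusted p = 2.14e-06; adjusted p = 0.178 with an estimated correlation). Of the 4 cell death genes limma called 0 (1 when adjusted over the list alone; camera adjusted p = 0.0223; adjusted p = 0.315 with an estimated correlation), and DMP4 was at 6.13 in time-course A, 0.34 in B and 0.55 in C. The list of laccases and peroxidases, with peroxidases alone measured, had 2 of 5 up (2 when adjusted over the list alone; camera adjusted p = 0.018; adjusted p = 0.147 with an estimated correlation). Nuclear photosynthesis genes had 7 of 23 down, with CaS at -2.82 ± 0.16 (camera adjusted p = 9.04e-12; adjusted p = 0.00755 with an estimated correlation). Of 28 tubulin and cortical microtubule genes 2 were down (camera adjusted p = 0.00378; adjusted p = 0.0323 with an estimated correlation), and the limma call of TUB5 (-1.60 ± 0.42) was lost without any of 4 arrays, with adjusted p up to 0.192 without the 96 h array of time-course A. In all, 1025 probe sets changed, 340 up and 685 down. The count was 612 without the 96 h array of time-course A, 1554 with the time-courses as a block and 31 in a fit to the 6 arrays alone. The mean 3′ minus 5′ GAPDH difference was 2.01, and the count was 411 without time-course B and 1677 with that difference as a covariate, both chosen after seeing the data.

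The comparison of 72 h with 48 h set the phase of wall deposition against the time before it. AT1G63310 rose by 3.29 ± 0.34 log2 units (SE, n = 3), the purple acid phosphatase gene PAP20 by 2.21 ± 0.39, AT5G53820 by 2.16 ± 0.41, AT1G23140 by 1.80 ± 0.35 and AT5G17160 by 1.68 ± 0.31. IRX10 rose by 1.40 ± 0.29 and GH3.3 by 1.17 ± 0.22. EXPA8 fell by 2.41 (SE 0.27) and AGL28 by 2.67 (SE 0.36). AT2G34060 (-3.48 ± 0.61), AT1G09390 (-3.23 ± 0.27), AT5G56980 (-3.13 ± 0.40) and AT5G02140 (-2.76 ± 0.38) also fell. The secondary wall polysaccharide list had 1 of 3 genes up (3 when adjusted over the list alone; camera adjusted p = 1.14e-06; adjusted p = 0.0145 with an estimated correlation). The wall loosening list had 1 of 4 down, EXPA8 (1 when adjusted over the list alone; camera adjusted p = 0.00118; adjusted p = 0.0145 with an estimated correlation). Its members EXPA9 and EXPA15 lay near the floor and EXPA4 was not called, so the list result rests largely on EXPA8. Xylem co-expressed genes had 1 of 19 up (camera adjusted p = 1.26e-07; adjusted p = 0.125 with an estimated correlation). The 28 chromosome replication and segregation genes had 0 members called by limma in this comparison and a median of 0.47, with camera adjusted p = 2.87e-07 and adjusted p = 0.0465 with an estimated correlation. The 6 core histone genes had 0 called and a median of 0.31 (camera adjusted p = 0.00119; adjusted p = 0.0347 with an estimated correlation).

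In that comparison of 72 h with 48 h, 100 probe sets changed (36 up, 64 down), against 1346 with an unadjusted p under 0.05 over all probe sets. With each of the 6 arrays left out in turn, the limma calls of PAP20, AT5G53820, AT1G23140, AT5G17160, IRX10 and GH3.3 were lost for 1, 4, 4, 2, 5 and 3 arrays. The highest adjusted p were 0.0523, 0.105, 0.116, 0.113, 0.187 and 0.104 in the same order. Leaving out any of the 6 arrays gave 55 to 64 probe sets (61, 56 and 55 without the 48 h arrays of A, B and C, and 64, 58 and 59 without those of 72 h), the block gave 155, and leaving out time-course B, chosen after seeing the data, gave 10.

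Between 72 h and 96 h the labels place the completion of the wall. Limma called 1 probe set, which is unnamed here and was singled out after its values were seen. It rose from 1.60 at 72 h to 4.13 at 96 h (2.53 ± 0.35 log2 units, SE, n = 3; adjusted p = 0.00943), having stood at 3.97 at 0 h and 0.50 at 48 h. At an unadjusted p under 0.05 there were 888 probe sets. PRX66 and IRX15, with differences of -1.85 ± 0.61 and -1.37 ± 0.45, and AT1G79620, with -2.01 ± 0.62, did not pass the test. The secondary wall polysaccharide list had 0 of 3 called (2 down when adjusted over the list alone) with a median of -0.85 (camera adjusted p = 0.00129; adjusted p = 0.115 with an estimated correlation). The xylem co-expressed list had 0 of 19 called and a median of -0.39 (camera adjusted p = 2.39e-05; adjusted p = 0.247 with an estimated correlation), and the autophagy list 0 of 10 and a median of 0.50 (camera adjusted p = 1.74e-05; adjusted p = 0.096 with an estimated correlation). The autophagy list did not pass when the 96 h array of time-course A was left out, a choice made after seeing the data (median 0.19, camera adjusted p = 0.159). Without the 96 h array of time-course A, 231 probe sets changed, and without the 72 h array of A or B or the 96 h array of B or C, 0 did. The block gave 9.

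Across the whole time-course the F test called 5254 of 22743 probe sets, and 2350 without time-course B and 1322 without C. The 3 measured reference genes (SAND, UBC21 and TIP41) had 0 limma calls in the 10 comparisons, also when adjusted over the list alone. The 3 procambium genes (PHV, LHW and BRL1) had 0 limma calls in the 10 comparisons (1 up at 48 h when adjusted over the list alone; camera adjusted p = 0.714). Of the 2 measured cytokinin response genes ARR16, and the hypoxia gene HRA1, lay near the floor on every array (at most 0.39 and 0.74), so that their response could not be read. The senescence list had 1 of 3 genes called down at 60 h, SAG101, which lay near the floor on every array (at most 1.01). Of the markers of other cell types, 2 phloem genes were measured, of which CLE41 fell at 48 h and 96 h as given above and SWEET11 lay near the floor (0.31 to 1.18), and LHCB4.1, of the photosynthesis list, was lower at 60 h (-1.21 ± 0.36), with 1.87 against 1.98 at 0 h in time-course A. Class III peroxidases moved both ways, with 9 of 55 up and 5 down at 60 h (camera adjusted p = 0.279). Plastid-encoded genes had 0 of 69 called at 48 h with a median of -0.40 (camera adjusted p = 6.10e-04; adjusted p = 0.725 with an estimated correlation). Mitochondrion-encoded genes had 0 of 15 called between 72 h and 96 h with a median of 0.53 (camera adjusted p = 0.0193; adjusted p = 0.732 with an estimated correlation). Of 15 SWEET genes SWEET17 fell at 48 h (-1.73 ± 0.30), of 7 exocyst genes SEC10 was lower at 12 h (-0.58 ± 0.18), and of 19 auxin-linked genes 4 were up at 48 h (camera adjusted p = 0.00231; adjusted p = 0.0191 with an estimated correlation). The SEC10 call was lost without any of 4 arrays, with adjusted p up to 0.191 without the 0 h array of time-course C.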

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

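The tests of the 3′ minus 5′ GAPDH difference and of the other control pairs, as a covariate and along the leading axis between arrays, the share of that axis taken by the letter, the difference between time-courses A and C along it, the leaving out of arrays for overlaps and for phosphate starvation genes, the count of time-courses closer to 0 h at 96 h than at 48 h, the mean squared differences with an array or a time-course left out, the assignments within letters for the F test, the simulations with independent effects, and the comparisons of 96 h with 12 h and with 48 h were chosen only after the result was seen.

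Genes that stood on opposite sides of their 0 h level at 12 h and at 96 h were singled out by the test of 96 h against 12 h. There were 46 probe sets up at 12 h, down at 96 h and lower at 96 h than at 12 h. Among them FDH, a formate dehydrogenase gene, was at 2.33 ± 0.34 at 12 h and -3.26 ± 0.34 at 96 h (log2 difference from 0 h, SE, n = 3), the metallothionein gene MT1C at 2.44 ± 0.60 and -2.40 ± 0.60, AT1G21520 at 2.69 ± 0.45 and -2.38 ± 0.45, and AT3G21690 at 3.45 ± 0.20 and -1.30 ± 0.20. In the opposite order there were 16 probe sets, among them the cellulase gene GH9B13 (-2.75 ± 0.50 and 2.34 ± 0.50). Neither count exceeds what chance gives. Independent lists of these sizes would share 58.1 and 29.5, and 20 simulations that kept the size of the effects and the sharing of 0 h values, but dealt the effects at 96 h to other probe sets, gave 31 to 51 and 13 to 30. Simulations of unchanged groups gave at most 0, which says little because they hold almost no calls. Error in the shared 0 h arrays moves both differences the same way, which lowers such counts. The 46 became 25 without the 0 h array of time-course C and 70 without the 12 h array of A, and the 16 became 10, 9 and 8 without the 0 h arrays of A, B and C. The count at 96 h was 612 without the 96 h array of time-course A.

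Relabelling the 6 arrays of a comparison gives 10 splits into 3 and 3, too few for a share under 0.05. The real split was 1 of the 10 with as many probe sets called at each of the 8 later times against 0 h and at 72 h against 48 h, and 3 of the 10 gave as many for 96 h against 72 h. The highest other split gave 91 (3900 real) at 12 h, 4 (2776) at 24 h, 12 (3075) at 36 h, 0 (2660) at 48 h, 329 (3008) at 60 h, 0 (1494) at 72 h, 5 (1434) at 84 h, 38 (1025) at 96 h, 0 (100) for 72 h against 48 h and 49 (1) for 96 h against 72 h. The counts of 0 are from limma, whose real comparisons held 5033, 3692 and 1346 probe sets at an unadjusted p under 0.05 at 48 h, at 72 h and for 72 h against 48 h. Because the letters pair the samples, the real split is best set against the splits that part every letter. These gave at most 70, 4, 2, 0, 7, 0, 0, 17, 0 and 0 in the same order. The split with 49 calls, many times the real count for 96 h against 72 h, put the 96 h array of time-course A with the 72 h arrays of A and C. Putting that array with the 72 h arrays of A and B gave 26, and with those of B and C 0. Both of the higher splits keep the arrays of A together and point to a structure between the arrays that includes the 96 h array of A. For the F test 1 of 100 assignments of the arrays to times, the real one, gave as many as 5254, and the highest other gave 1423. Of 100 assignments that moved arrays only within their letter, the highest other gave 1180. Chance is an unlikely cause there, though a share of 1 in 100 is the smallest that 100 assignments can give.

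Fewer probe sets differed from 0 h at 96 h (1025) than at 48 h (2660). The tables argue against a loss of 5′ signal on some arrays as the whole cause. With the GAPDH covariate the count at 96 h was 0.540 of that at 48 h. The mean squared difference less its error was at 96 h 0.480 of that at 48 h, so the differences themselves were smaller. That error is pooled over all arrays and is the same at both times, so this ratio cannot decide on a larger spread at 96 h. The tables also argue against an effect of 1 time-course alone, since this ratio was at most 0.587 with any time-course left out. The count of time-courses closer to their 0 h array at 96 h than at 48 h, 2 of the 3, was undecided because all 3 had been required (root mean square log2 difference 0.893 against 1.37 in B and 0.962 against 1.45 in C, but 1.34 against 1.24 in A). The ratio was 0.341 without the 96 h array of time-course A, which argues against a wrong time label on that array as the cause. Whether its label is right stays open: it correlated best with the 72 h mean of the others (r 0.463, against -0.0831 with their 96 h mean). In 3 other arrays an earlier time also matched best, by less (60 h of A with 48 h, 0.558 against 0.520; 96 h of C with 84 h, 0.523 against 0.496; and 36 h of A with 24 h, with 0.627 at its own time), and a delay of the culture in time-course A stays open beside a wrong label. For 96 h of C the mean at its own time includes the 96 h array of A, so that match is not independent of it. Though a best time of 72 h had been taken in advance as evidence against a wrong label, that bound was ill chosen because 72 h is not the label either. A later stage of the culture, which the design names, remains a candidate explanation that was not tested on its own.

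Arrays of the same time differed along 1 leading axis, which held 31.9% of the variance left after the time means. The tables argue against a constant difference between the 3 time-courses as the whole cause. The share of the variance of the axis taken by the letter, 0.704, was undecided between the bounds of 0.5 and 0.8 set for it, but the difference between time-courses A and C along it ran from -40.4 to 16.0 over the 9 times and followed their difference in GAPDH (Pearson correlation 0.857, exact permutation p = 0.00421). A loss of 5′ signal on some arrays remains a candidate explanation, with tests of unequal outcome: over the 22 arrays with a GAPDH difference under 2.5, the position on the axis and that difference had a Pearson correlation of 0.519 (permutation p = 0.013; 0.427 without the 2 farthest arrays), between the bounds of 0.3 and 0.6 set for it. That permutation shuffled the 22 arrays freely, so its p does not allow for their grouping by time-course. Along the axis that sets the 5 arrays of time-course B apart, a test between time-courses A and C over 9 times, chosen after that undecided result, gave 0.883 (exact permutation p = 0.00202; 0.633 without the 2 farthest times). The 4 other control pairs gave a median of 0.702, with 0.682 and 0.828 and 0.722 for the second GAPDH, second actin and ubiquitin pairs but 0.330 for the first actin pair (exact permutation p = 0.044, 0.00524, 0.028 and 0.386). The 5 arrays with the highest GAPDH difference are all of time-course B, so a part due to that time-course stays open. No biological explanation was tested.

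Some genes that were high at 0 h, in 7 day old medium, were lower after the transfer and higher again at 96 h than at 48 h. AT5G20790 stood at 8.91, 4.60 and 7.38 log2 units at 0 h, 48 h and 96 h, AT1G23140 at 5.34, 1.22 and 4.77, and OCT1 at 7.21, 0.40 and 4.38 (adjusted p of the later rise 0.00944, 7.79e-06 and 0.0383 by limma). The rise of AT5G20790 was lost without the 96 h array of time-course B or C (adjusted p = 0.0925 and 0.0667), and that of OCT1 without any of the 5 arrays of 48 h and 96 h other than 96 h of A (adjusted p up to 0.276 without 96 h of B). The later rise of AT1G13750, from 0.61 to 2.63, did not pass (adjusted p = 0.151). At 96 h time-course A stood below B and C in these genes, with AT1G13750 at 0.33, 3.91 and 3.65 and AT5G20790 at 5.43, 8.21 and 8.51, and without that array AT1G13750 rose (adjusted p = 5.12e-05 by limma, SE 0.41). A candidate explanation of the high level at 0 h is phosphate depletion of the old medium: of 3 phosphate starvation genes whose values had not been seen, 2 were lower at 48 h than at 0 h (AT1G08310 by -2.35 ± 0.30 and AT5G09570 by -2.48 ± 0.39), while SAL2 stood near the floor. Of these AT5G09570 was back at 9.06 at 96 h against 9.14 at 0 h (adjusted p of the later rise 0.00216 by limma), but AT1G08310 stood at 2.84, 0.49 and 1.46 and its later rise did not pass (adjusted p = 0.155; 0.00839 without the 96 h array of A), so a depletion of the new medium is left open. For the fall by 48 h the tables argue against a loss of 5′ signal on some arrays, since 4 of the 4 genes seen first were still lower with the GAPDH covariate. The later rise at 96 h was not tested with that covariate. Medium age was not varied on its own, so this remains a hypothesis.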

How the results depend on the processing

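The GAPDH covariate, without and with the block, and the leaving out of time-course B or of the 5 arrays of low 5′ signal were chosen after seeing the data. Of 170 called values of named genes 0 reversed under any setting, and 170 stayed called with the time-courses as a block, 167 with arrays centred on their median, 161 after quantile normalization, 170 without dim probe sets, 164 with a 2-fold minimum, 138 at an adjusted p under 0.01, 168 with trend and robust options, 167 with array weights, 169 with the covariate, 117 without time-course B, 144 without the 5 arrays and 111 in fits to the 6 arrays compared. With each array left out in turn 39 of them were lost for at least 1 array. The values had been chosen as called, and the largest rises and falls also for the same sign in all time-courses. Few reversals could therefore occur. Of 85 list calls, 33 held with an estimated correlation, 81 with the block, 63 with directional fry, 48 with mixed fry and 78 with the covariate. With the block plastid-encoded genes also passed at 24 h, 36 h, 60 h and 96 h (adjusted p = 0.00296, 0.00655, 0.00838 and 0.0116), mitochondrion-encoded genes at 96 h (0.00911) and microtubule genes for 72 h against 48 h (0.0374).

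Counts that moved by over 1.5 times follow, against 0 h unless named. With a 2-fold minimum they were 2554 at 12 h, 1773 at 24 h, 1926 at 36 h, 1681 at 48 h, 1797 at 60 h and 922 at 84 h. At an adjusted p under 0.01 they were 1648 at 24 h, 1757 at 36 h, 1512 at 48 h, 1695 at 60 h, 819 at 72 h, 725 at 84 h, 515 at 96 h, 52 for 72 h against 48 h and 3458 for the F test. With the block they were 1554 at 96 h, 155 for 72 h against 48 h and 9 for 96 h against 72 h, and the block moved no other count by as much. Array weights gave 4248 at 24 h, 4032 at 48 h, 2570 at 72 h, 2833 at 84 h, 306 for 72 h against 48 h and 142 for 96 h against 72 h. The covariate gave 2266 at 72 h, 2210 at 84 h, 1677 at 96 h and 6 for 96 h against 72 h, and with the block 2670, 2588, 2055 and 11, with 164 for 72 h against 48 h. Without time-course B they were 1753 at 24 h, 1560 at 36 h, 1388 at 48 h, 1546 at 60 h, 698 at 72 h, 604 at 84 h, 411 at 96 h, 10 for 72 h against 48 h and 0 for 96 h against 72 h. Without the 5 arrays they were 61 for 72 h against 48 h and 0 for 96 h against 72 h. Fits to the 6 arrays gave 2243 at 12 h, 973 at 60 h, 763 at 72 h, 659 at 84 h, 31 at 96 h, 220 for 72 h against 48 h and 0 for 96 h against 72 h. For 96 h against 72 h, 3 were called without dim probe sets and 6 with trend and robust options. The counts of 0 are from limma, and the comparison held 888 probe sets at an unadjusted p under 0.05 with all arrays. The causes were not tested, except that fewer arrays leave less to estimate the spread from.

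With each array left out in turn the counts ran from 3072 to 3726 at 12 h, 2032 to 2763 at 24 h, 2186 to 2960 at 36 h, 1837 to 2752 at 48 h, 2110 to 3272 at 60 h, 993 to 1695 at 72 h, 945 to 1480 at 84 h, 612 to 1158 at 96 h, 55 to 64 for 72 h against 48 h and 0 to 231 for 96 h against 72 h, and from 1322 to 5502 for the F test with each time-course left out. Low signals limit what could be seen, since values stop at 0 and array medians were 1.00 or less.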

Other observations

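The comparisons of 24 h with 12 h, of 96 h with 48 h, the simulations with independent effects, the overlaps with arrays left out, and the genes and lists found without the 96 h array of time-course A were chosen only after the result was seen.

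Part of the response at 12 h had turned back by 24 h, and whether it reached the 0 h level was not tested. Of the 1929 probe sets up at 12 h, 993 were lower at 24 h than at 12 h by the test of these times, against 141 for independent lists, and of the 1971 down at 12 h, 606 were higher again at 24 h, against 105. Of the 1527 probe sets down at 48 h, 115 were higher at 96 h than at 48 h (9.94 for independent lists), among them the defensin-like gene LCR68 (4.02 ± 0.55 log2 units, SE, n = 3) and AT5G17340 (4.68 ± 0.77). Of the 1133 up at 48 h, 111 were lower at 96 h (6.63 for independent lists), among them PRX52 (-2.71 ± 0.63), AGL28 (-2.51 ± 0.36), EXPA8 (-2.35 ± 0.27) and AT1G09390 (-3.45 ± 0.27). The comparison of 96 h with 48 h called 281 probe sets, 668 without the 96 h array of time-course A and 98 without that of B. The 115 and 111 became 303 and 258 without 96 h of A, and 36 and 49, 58 and 65, 61 and 55, 54 and 50, and 49 and 55 without 96 h of B, 96 h of C and 48 h of A, B and C. Each pair of comparisons shares arrays at its middle time, whose error favours such overlaps. In 20 simulations that kept this sharing and the size of the effects, but dealt the effects of the second comparison to other probe sets, the overlaps were at most 127, 97, 19 and 10 in the same order. Simulations of unchanged groups gave at most 0, which says little because they hold almost no calls.

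At 96 h time-course A stood apart from B and C, in genes linked to xylem and in others. DMP4 was at 6.13 in A, 0.34 in B and 0.55 in C, PRX66 at 7.58, 3.96 and 4.47, AT3G27200 at 8.19, 3.28 and 3.66, OCT1 at 1.11, 6.17 and 5.85, GSTU25 at 7.34, 1.69 and 1.20, HSP22 at 2.77, 0.56 and 0.65, XTH32 at 1.99, 4.53 and 4.64, and AT4G39320 at 3.64, 7.67 and 7.60. Without the 96 h array of A, left out because it stood apart, 231 probe sets differed between 72 h and 96 h (124 up, 107 down). PRX66 (-2.97 ± 0.41), AT5G38610 (-3.14 ± 0.26) and AT1G79620 (-2.98 ± 0.51) fell, as did AT3G27200, and OCT1 rose by 4.73 ± 0.70, LCR68 by 3.89 ± 0.53 and AT1G13750 by 3.13 ± 0.41. Of the 19 xylem co-expressed genes 8 fell (camera adjusted p = 2.53e-18; adjusted p = 3.83e-06 with an estimated correlation), as did 2 of the 3 secondary wall polysaccharide genes (camera adjusted p = 1.10e-06; adjusted p = 0.00898 with an estimated correlation). Of the 4 cell death genes 0 were called by limma (camera adjusted p = 0.0067; adjusted p = 0.0686 with an estimated correlation). Other lists that passed there with 0 members called were mitochondrion-encoded genes and expansins and xyloglucan endotransglucosylases, both up, and chromosome replication and segregation, down (camera adjusted p = 0.0226, 0.0278 and 0.0242; adjusted p = 0.711, 0.38 and 0.38 with an estimated correlation). These values rest on 2 arrays at 96 h. The array left out was chosen for standing apart in such genes, which favours these differences. Their p-values are therefore no separate test of a change between 72 h and 96 h. With all arrays limma called 1 probe set in that comparison, which is unnamed here.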
